A study of Mus musculus with 6 samples.

How the data were processed

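Messenger RNA was measured in cultured mouse neural stem cells, the self-renewing precursors of neurons and glia, taken from the embryonic hippocampus at day 14 of gestation. Per the labels, the cells had been infected with a lentivirus that carried either a control siRNA, called circCon, or an siRNA against circHIPK2. circHIPK2 is a circular RNA formed from the Hipk2 gene. There were 3 libraries per group. Per the labels' protocols, RNA was extracted with TRIzol and selected with oligo-dT beads, and strand-marked libraries (dUTP) were sequenced from both ends on an Illumina NovaSeq instrument. The adapters held unique molecular identifiers. Whether these identifiers were used to remove duplicates is not given in the sources used here.

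The deposited table held FPKM values, which are fragments per kilobase of transcript per 1000000 mapped fragments, for 54884 entries in the 6 libraries. Per the submitters' processing notes, HISAT, StringTie and edgeR were used with the mm9 genome build. The versions, the gene annotation, the use of strand and the part each tool played are not given in the sources used here. Entries were named by gene symbol alone. Of these, 98.54% carried a symbol found in GENCODE M21, an annotation of the later GRCm38 build, so no coordinates are given. A spreadsheet had turned 26 symbols into dates, and these entries could not be traced to a gene. There were 2 symbols with more than 1 entry.

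Raw counts were not used here. Depth was read from the low FPKM values of genes with 1 annotated transcript of at least 500 nt, on the assumption that these are whole multiples of the value of 1 fragment. Between 39.3% and 43.6% of the low values of a library lay within 0.05 steps of a whole multiple, against 10% by chance. The steps gave 19810000, 21910000 and 21380000 fragments for control libraries 1 to 3 and 18330000, 20990000 and 20050000 for circHIPK2 siRNA libraries 1 to 3. The deepest library was 1.2 times the shallowest. At these depths 1 fragment of a 1 kb transcript is worth between 0.0456 and 0.0546 FPKM, so values under about that level rest on single fragments.

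The comparison was circHIPK2 siRNA against control. FPKM values were used as deposited, with 1 added before taking log2, for the 13702 entries with a mean of at least 1 FPKM over all libraries. Groups were compared with limma 3.58.1 in R 4.3.3 (moderated linear model with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over all entries tested. A gene was called at an adjusted p below 0.05, with no minimum fold. Every log2 fold change is on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes. Folds are ratios of mean FPKM. Exact permutation tests of 3 against 3 libraries cannot give a two-sided p below 0.1.

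There were 26 gene lists, covering neural cell types, other cell types, the cell cycle, stress, signalling and metabolism. The 24 lists with at least 5 tested members were tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01. Members were also adjusted over the list alone. The alternatives were camera with a correlation estimated from the libraries, and fry, which asks whether a list's own genes move, on balance, one way.

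The lists, the main test, the alternatives and the rule for naming genes were fixed before the data were examined. Named were Hipk2, the other 3 Hipk genes with an entry and Smox. Also named were the 10 largest rises and 10 largest falls past the threshold whose libraries did not overlap between groups, leaving out Gm, Rik, clone and pseudogene names. For each list the rule took up to 2 called members per direction, or otherwise the member with the highest mean FPKM. Other genes were chosen after their values were seen, and this is said where they appear. A few genes that passed or that the rule takes are not reported here.

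The alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, columns rescaled to a sum of 1000000, limma without the trend, with robust moderation or with library weights, the replicate number as a block, 1 entry per symbol, thresholds with a fold of at least 2, and each library left out in turn. Added after seeing the data were removal of 9 entries at or rising with the ribosomal RNA locus, removal of liver genes, and a loess correction for transcript length and GC content, which were known for 99.5% of the entries tested.

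The same steps were tested on simulated data with the means and spreads of these 13702 entries, with 200 changed genes in each of 10 runs. At 1.5-fold, 2-fold and 4-fold, 36%, 84.3% and 97.4% of the changed genes were recovered, and 6.5% of the calls were false. A list of 40 genes shifted by 0.3 on the log2 scale was called in 10 of 10 runs, and an unshifted list in 0. The simulated genes varied independently, whereas the correlation estimated for the called lists was between 0.10 and 0.72. The simulation therefore does not show how often the list test calls falsely on these libraries.

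For the closing tests, transcript sequences and 3' UTRs of GENCODE M21 were used, with blastn 2.17.0 for shared sequence. UTRs of at least 50 nt were known for 81.2% of the tested genes and were scanned for 7-mers, and the scan recovered a planted 7-mer in simulated data. Further marker lists, written after the calls had been seen, held hepatocyte genes outside the calls, fetal liver and erythroid genes, intestinal, kidney, muscle and pancreatic genes, non-polyadenylated small RNAs, and histone genes of the replication-dependent class. A gene of these lists counted as detected at a mean of at least 0.02 FPKM. These steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.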

Results

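Expression was measured by poly(A)-selected RNA sequencing in 6 libraries of embryonic mouse hippocampal neural stem cells, 3 with a control siRNA and 3 with an siRNA against the circular RNA circHIPK2. Depth, read from the steps of the FPKM values, was between 18330000 and 21910000 fragments per library. Nothing states that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. The first principal component held 43.3% of the variance and separated the 3 control from the 3 siRNA libraries, and the second held 17.2%. On the first, siRNA libraries 1 to 3 scored 13.8, 3.26 and 27.8. They ranked as they did by share of FPKM in the 9 entries at or rising with the ribosomal RNA locus (11.5%, 3.24% and 19.9%). These entries and the liver genes were included, so the separation is not that of an siRNA effect alone. Pearson correlations of libraries across genes, which are not independent replicates, were between 0.983 and 0.986 within groups and between 0.975 and 0.983 across groups.

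The comparison asks which transcripts of neural stem cells change when circHIPK2 is silenced. Hipk2, the protein kinase gene from which the circle is made, was measured at 31.8, 36.9 and 30.9 FPKM in control libraries 1 to 3 and at 28.3, 28.8 and 23.8 FPKM in siRNA libraries 1 to 3. Its mean was 33.2 ± 3.23 FPKM in the controls and 27.0 ± 2.78 FPKM with the siRNA (SD, n = 3 each). The log2 fold change was −0.29 (SE 0.11), which did not pass the test (adjusted p = 0.257, limma with Benjamini-Hochberg adjustment). The libraries did not overlap on the values as deposited (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). On that scale 22.1% of all genes tested lay entirely lower with the siRNA, so this sets Hipk2 little apart. Over other settings its log2 fold change ranged from −0.34 to −0.09. The gene value is that of the mRNA and is not a measurement of circHIPK2, so it checks neither the silencing of the circle nor the group labels. The related kinase genes Hipk1 and Hipk3 had log2 fold changes of −0.24 (adjusted p = 0.352, limma with Benjamini-Hochberg adjustment) and −0.09 (adjusted p = 0.637), and the sign for Hipk3 turned under the median-of-ratios and quantile scalings. Hipk4 had 0.0941 ± 0.0409 FPKM in the controls and 0.114 ± 0.0541 FPKM with the siRNA, below the filter.

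Smox, which encodes spermine oxidase of the polyamine pathway and is a gene the study followed up, had 55.6, 69.3 and 47.1 FPKM in control libraries 1 to 3 and 39.3, 37.5 and 8.34 FPKM in siRNA libraries 1 to 3. Its means were 57.3 ± 11.2 and 28.4 ± 17.4 FPKM (SD, n = 3 each), 2.02-fold apart. The log2 fold change of −1.24 (SE 0.50) did not pass the test (adjusted p = 0.26, limma with Benjamini-Hochberg adjustment; exact permutation p = 0.1, the smallest possible). Without siRNA library 3 it was −0.55 (adjusted p = 0.327). The study followed up Smox after this RNA sequencing and may have chosen it on these libraries, so its direction is not independent evidence.

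**Figure D1:**
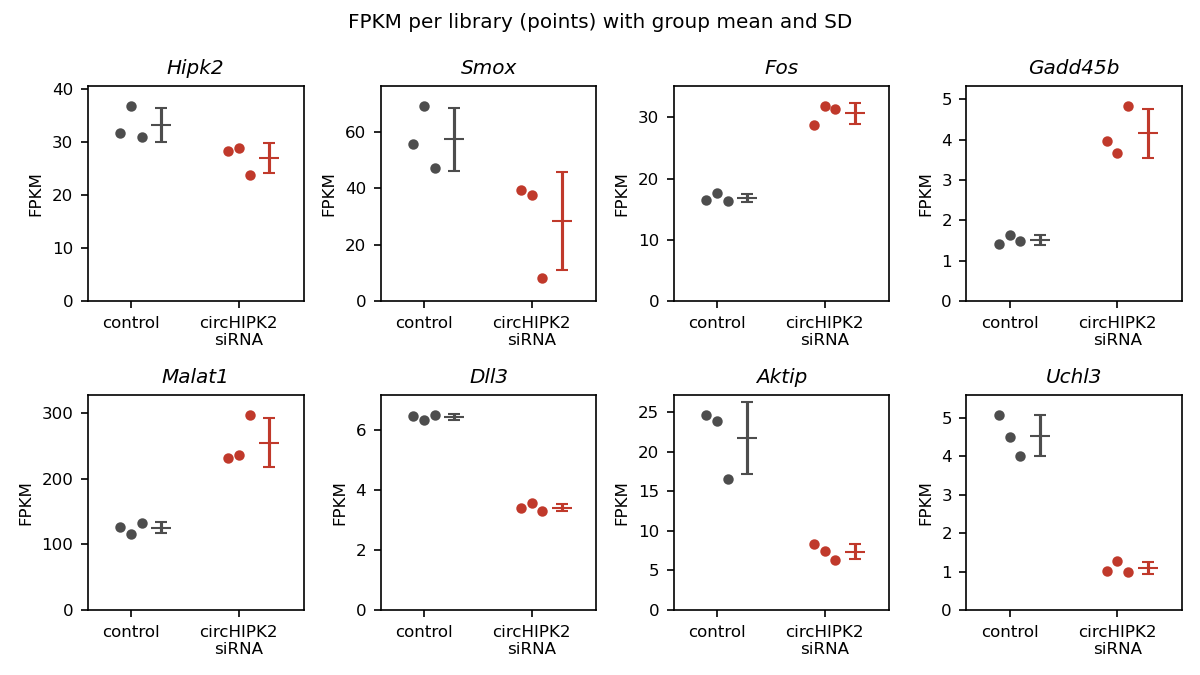
FPKM of 8 genes per library (points; vertical axis from 0), with the group mean and SD (horizontal mark and bar) for 3 control (grey) and 3 circHIPK2 siRNA (red) libraries. For Smox, siRNA library 3 at 8.34 FPKM lies apart from the other siRNA libraries at 39.3 and 37.5 FPKM, and Fos rose from a mean of 16.8 to 30.7 FPKM.

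With circHIPK2 siRNA 16 genes rose and 19 fell among 13702 tested. Among the rises were Fos, an AP-1 transcription factor induced by growth signals, from 16.8 ± 0.69 to 30.7 ± 1.71 FPKM (1.82-fold), and Gadd45b, a stress-induced growth arrest gene, from 1.51 ± 0.12 to 4.16 ± 0.61 FPKM (2.76-fold). Rgs16, a regulator of G-protein signalling, rose from 4.58 ± 0.51 to 10.3 ± 1.07 FPKM, and Cacng5, an auxiliary subunit of AMPA receptors, from 3.78 ± 0.68 to 8.72 ± 0.56 FPKM (SD, n = 3 each). Syt4, a synaptotagmin of secretory vesicles, rose from 0.508 ± 0.17 to 2.29 ± 0.37 FPKM. The nuclear long noncoding RNA Malat1 rose from 125 ± 8.49 to 255 ± 37.0 FPKM. Gm27694, annotated within Malat1 on the same strand, rose with it, so the pair cannot be counted as independent. Rpl21, a ribosomal protein gene whose reads may be split with pseudogene copies, rose from 6.95 ± 0.75 to 13.2 ± 0.24 FPKM. The adjusted p-values of these genes lay between 0.0134 for Fos and 0.0187 for Malat1 (limma with Benjamini-Hochberg adjustment), with log2 fold changes from 0.83 for Fos (SE 0.09) to 1.12 for Syt4 (SE 0.14).

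The other 8 rises were the largest and rose together. AY036118 rose from 972 ± 271 to 29273 ± 20362 FPKM (30.1-fold; log2 fold change 4.60, SE 0.58) and CT010467.1, annotated as ribosomal RNA, from 558 ± 186 to 17960 ± 14918 FPKM (32.2-fold). The Lars2 entry, named for the mitochondrial leucyl-tRNA synthetase, rose from 19.3 ± 3.70 to 463 ± 305 FPKM and shares 72 nt with Gm15564, which also rose. Gm26917, annotated beside AY036118, rose as well, as did Gm23935, Gm24270 and Gm24187, which share sequence with one another, and these 5 Gm entries are outside the naming rule. Gm42418, which lies antisense to AY036118 and was chosen after its values were seen, had 403 ± 166 and 1432 ± 374 FPKM and did not pass (adjusted p = 0.0844, limma with Benjamini-Hochberg adjustment). Use of strand is not stated, so reads cannot be assigned among entries that overlap or share sequence, and sequence shared with ribosomal RNA was not shown for Gm26917 or the 5 entries elsewhere. Together the 9 entries took 0.58%, 0.43% and 0.32% of all FPKM in control libraries 1 to 3 and 11.5%, 3.24% and 19.9% in siRNA libraries 1 to 3.

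**Figure D2:**
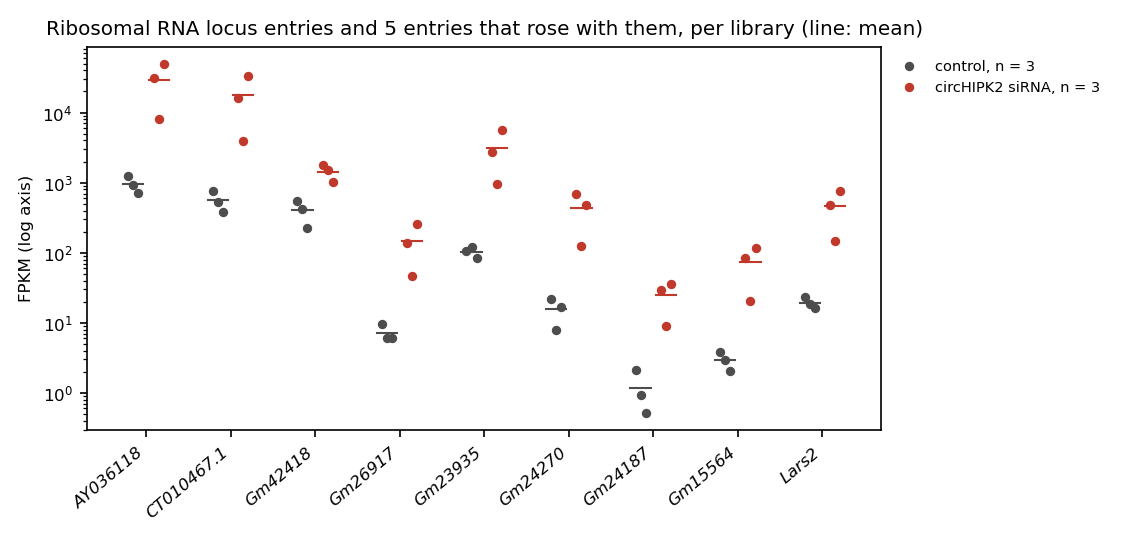
FPKM on a log axis of 4 entries at the ribosomal RNA locus or beside it (AY036118, CT010467.1, Gm42418 and Gm26917) and of 5 that rose with them, per library (points) with group means (lines), for 3 control (grey) and 3 circHIPK2 siRNA (red) libraries. For each entry the 3 siRNA libraries lie above the 3 controls, and AY036118 has means of 972 and 29273 FPKM.

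Of the 19 falls, 10 were of genes known for expression in the liver. Alb, which encodes serum albumin, had 20.1, 15.8 and 21.6 FPKM in control libraries 1 to 3 and 0.0365, 0.0581 and 0.12 FPKM in siRNA libraries 1 to 3 (adjusted p = 4.68e-06, limma with Benjamini-Hochberg adjustment; log2 fold change −4.22, SE 0.13). The apolipoprotein genes Apoa1, Apoa2 and Apoc1 had control means of 4.54 ± 2.35, 10.5 ± 3.70 and 2.46 ± 0.72 FPKM and siRNA means of 0.0545, 1.89 and 0.0682 FPKM. Fabp1, the liver fatty acid binding protein, and Serpina1c, an alpha-1-antitrypsin gene, had control means of 3.23 ± 1.11 and 2.92 ± 0.71 FPKM and were listed at 0 in the 3 siRNA libraries. Serpina1a and Serpina1b, near-identical copies of Serpina1c whose reads may be split among them, also fell, from 2.29 and 3.06 FPKM. Ttr, the transthyretin carrier of thyroid hormone, fell from 3.10 ± 0.62 to 0.0781 FPKM, and Ahsg, which encodes fetuin-A, from 2.36 ± 0.72 to 0.00209 FPKM. The siRNA means of these genes other than Apoa2 lie within a few fragments of 0.

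**Figure D3:**
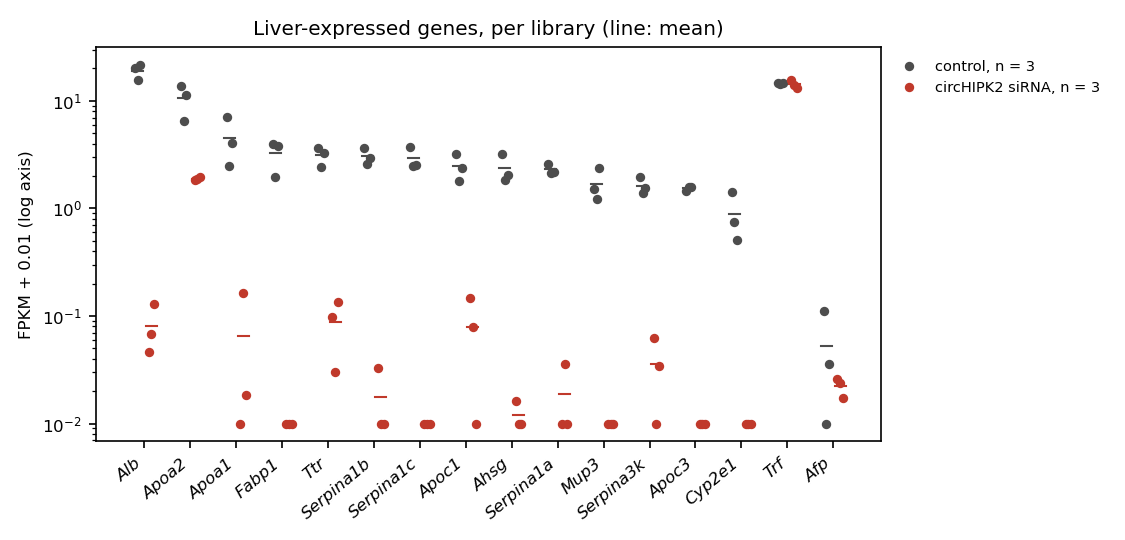
FPKM + 0.01 on a log axis of 16 genes with known liver expression, per library (points) with group means (lines), for 3 control (grey) and 3 circHIPK2 siRNA (red) libraries. Alb lies between 15.8 and 21.6 FPKM in the controls and at or below 0.12 FPKM with the siRNA, while Trf overlaps between groups.

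The other 9 falls were of genes outside this group. Dll3, a Notch ligand of differentiating neural progenitors, fell from 6.45 ± 0.092 to 3.42 ± 0.13 FPKM (log2 fold change −0.75, SE 0.09; adjusted p = 0.0154, limma with Benjamini-Hochberg adjustment). Those that follow were named after their values were seen, being outside the rule. Uchl3, a ubiquitin hydrolase, fell from 4.53 ± 0.53 to 1.09 ± 0.16 FPKM (4.17-fold), Lypd1, a membrane-anchored modulator of nicotinic receptors, from 6.17 ± 1.04 to 1.84 ± 0.041 FPKM, and Aktip from 21.7 ± 4.51 to 7.38 ± 0.97 FPKM. Mfsd2a, a lysophospholipid transporter, fell from 18.6 ± 1.27 to 9.51 ± 1.64 FPKM, and Mad2l2, a subunit of a translesion DNA polymerase, from 16.2 ± 2.25 to 7.87 ± 1.38 FPKM. Gm29521 fell from 6.16 ± 0.79 to 2.49 ± 0.045 FPKM and Ccnb1-ps, a cyclin B1 pseudogene that may share reads with Ccnb1, from 22.3 ± 1.16 to 14.1 ± 0.58 FPKM.

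The counts rested partly on single libraries and on the scaling. Without siRNA library 3, 2 genes rose and 6 fell; without control library 2 or 3, 10 and 8 rose, and without control library 1, 12 fell. With quantile normalization 4 rose and 12 fell, so that 25% of calls were higher against 45.7%. Of 34 called genes followed singly, 7 were called in each fit that left out 1 library and kept them above the filter: Alb, Serpina1a, Serpina1b, Serpina1c, Ttr, Uchl3 and Gm23935. The call was lost without siRNA library 3 for 27. Dll3, Mfsd2a, Mad2l2 and Ccnb1-ps were called in 0 of these 6 fits, in which the adjusted p of Dll3 ran from 0.0515 to 0.0829 (limma with Benjamini-Hochberg adjustment). Fos and Gadd45b were also lost without control library 3, to adjusted p = 0.0585 and 0.0544, and Malat1 was called in 1 of the 6. Of the 8 entries that rose together, CT010467.1 was called in 1 fit (adjusted p up to 0.129, limma with Benjamini-Hochberg adjustment), Gm15564, Gm24187 and Gm26917 in 2 (up to 0.114), AY036118 (up to 0.0859) and Gm24270 (up to 0.138) in 3, and Lars2 in 4. Syt4, Rpl21 and Gm27694 were called in 2, Aktip in 3, Fos, Gadd45b, Cacng5, Apoa1, Apoa2 and Gm29521 in 4, and Rgs16, Lypd1 and Fabp1 in 5. Ahsg and Apoc1 were called in 4 of 5. The highest adjusted p of the 34 was 0.193 (Ccnb1-ps, limma with Benjamini-Hochberg adjustment).

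Over all genes tested the median log2 fold change was −0.12, which median-of-ratios scaling brought to −0.00096. List medians, and counts of members above or below, are therefore given relative to it. Calls of single members, over all genes or over the list alone, tested a change from 0 on the values as deposited. Those calls are not relative to other genes, and the shift of all genes adds to the falls among them. At an unadjusted p below 0.05, 251 genes were higher and 2117 lower. The 3 siRNA libraries lay entirely above the controls for 363 genes and entirely below for 3027, together 24.7% against 10% by chance. The division between the directions depends on the scaling. With median-of-ratios scaling, which centres the median and so evens the directions, the counts were 1382 and 1381 (20.2%). Without the 9 entries at or rising with the ribosomal RNA locus, and with columns rescaled, the median was 0.058 and the counts were 1943 and 591.

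Immediate early and heat shock genes, inflammatory and NF-kB genes, interferon response genes and p53 target genes were higher relative to all other genes, as groups, with circHIPK2 siRNA (limma's camera with Benjamini-Hochberg adjustment). With an estimated correlation 0 of these 4 lists were called (adjusted p from 0.418 to 0.734). The 9 entries at or rising with the ribosomal RNA locus, at 3.24% to 19.9% of FPKM with the siRNA against 0.32% to 0.58%, were higher in the same libraries, and the liver transcripts were lower in them. Of 27 immediate early and heat shock genes, 25 lay above the median of all genes, with a list median 0.31 above it (adjusted p = 1.87e-13, limma's camera with Benjamini-Hochberg adjustment; adjusted p = 0.418 with an estimated correlation). Fos rose over all genes tested, and 8 members, all of them immediate early genes, rose when adjusted over the list alone. The 6 heat shock members tested had log2 fold changes from −0.30 for Hspd1 to −0.01 for Hspa1b, and 0 of them passed over all genes or over the list alone. Among the 8 immediate early genes, chosen after their values were seen, the transcription factor genes Egr1, from 50.8 ± 5.74 to 72.2 ± 4.13 FPKM, Klf4, from 1.69 ± 0.24 to 3.45 ± 0.39 FPKM, and Junb, from 2.44 ± 0.51 to 4.55 ± 0.91 FPKM, did not pass over all genes.

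Of 11 inflammatory and NF-kB genes, 9 lay above the median of all genes, by a list median of 0.35 (adjusted p = 1.2e-06, limma's camera with Benjamini-Hochberg adjustment; adjusted p = 0.418 with an estimated correlation). None passed over all genes, while 4 rose and 1 fell adjusted over the list alone. The chemokine gene Ccl2 (0.681 ± 0.29 and 1.93 ± 0.24 FPKM) and Nfkb2, an NF-kB subunit gene (4.85 ± 0.44 and 6.81 ± 0.13 FPKM), both chosen after their values were seen, were among the 4, with Nfkbia and Csf1; Nfkb1 was the member that fell. The member with the highest mean, the chemokine gene Cx3cl1, had 22.1 ± 2.64 and 22.1 ± 1.72 FPKM.

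Of 19 interferon response genes, 16 lay above the median of all genes, by a list median of 0.21 (adjusted p = 2.47e-06, limma's camera with Benjamini-Hochberg adjustment; adjusted p = 0.634 with an estimated correlation). None passed over all genes, and 2 rose adjusted over the list alone. These were Gbp2, an interferon-induced GTPase gene (0.536 ± 0.16 and 1.72 ± 0.28 FPKM), and Cxcl10, an interferon-induced chemokine gene (0.737 ± 0.25 and 2.45 ± 0.78 FPKM), both named after their values were seen. B2m, the light chain of class I antigen presentation, had 131 ± 11.8 and 134 ± 7.06 FPKM. With a minimum mean of 5 FPKM the list was not called (adjusted p = 0.076).

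Of 31 p53 target genes, 27 lay above the median of all genes, by a list median of 0.10 (adjusted p = 0.00026, limma's camera with Benjamini-Hochberg adjustment; adjusted p = 0.734 with an estimated correlation). Before subtracting that median the list median was −0.02 and its mean 0.03, so the list was less low than other genes and was not called higher in itself (adjusted p = 0.87, limma's fry with Benjamini-Hochberg adjustment). No member passed over all genes or adjusted over the list alone. Cdkn1a, the cell cycle inhibitor p21, had 288 ± 50.9 and 356 ± 49.5 FPKM, and Phlda3, an inhibitor of AKT signalling chosen after its values were seen, had 49.3 ± 1.33 and 61.5 ± 3.76 FPKM. The call was lost without control library 2 (adjusted p = 0.101), with no filter (0.256) and with library weights (0.213).

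Mitosis genes, S phase genes, cholesterol synthesis genes, nuclear genes of oxidative phosphorylation and cytosolic ribosomal protein genes were lower relative to all other genes, as groups, with circHIPK2 siRNA (limma's camera with Benjamini-Hochberg adjustment). With an estimated correlation 0 of these 5 lists were called (adjusted p from 0.634 to 0.734). The libraries in which they were lower were those with 3.24% to 19.9% of FPKM in the 9 entries at or rising with the ribosomal RNA locus and without the liver transcripts of the controls. Of 40 mitosis genes, 39 lay below the median of all genes, by a list median of −0.25 (adjusted p = 1.97e-13, limma's camera with Benjamini-Hochberg adjustment; adjusted p = 0.634 with an estimated correlation). Over all genes 0 passed, and 31 fell adjusted over the list alone. They included Kif2c, a kinesin of chromosome segregation (22.2 ± 1.77 and 14.3 ± 0.48 FPKM), and Nusap1, a spindle protein gene (34.1 ± 1.86 and 24.7 ± 1.35 FPKM), both chosen after their values were seen. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit and the most abundant member, had 70.6 ± 6.13 and 59.1 ± 7.93 FPKM.

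Of 36 S phase genes, 32 lay below the median of all genes, by a list median of −0.14 (adjusted p = 3.72e-06, limma's camera with Benjamini-Hochberg adjustment; adjusted p = 0.734 with an estimated correlation). None passed over all genes, and 6 fell adjusted over the list alone, among them the replication clamp gene Pcna (137 ± 15.6 and 95.6 ± 4.70 FPKM) and the helicase gene Mcm2, chosen after its values were seen (34.4 ± 3.77 and 26.0 ± 0.82 FPKM).

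Of 24 cholesterol synthesis genes, 20 lay below the median of all genes, by a list median of −0.28 (adjusted p = 5.23e-07, limma's camera with Benjamini-Hochberg adjustment; adjusted p = 0.734 with an estimated correlation). Over all genes 0 members passed, and 18 fell adjusted over the list alone. Hmgcs1, which makes HMG-CoA, had 251 ± 22.8 and 196 ± 20.03 FPKM. Insig1, a sterol sensor gene named after its values were seen, had 57.1 ± 6.60 and 38.7 ± 3.87 FPKM.

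Of 61 nuclear genes of oxidative phosphorylation, 53 lay below the median of all genes, by a list median of −0.15 (adjusted p = 2.95e-06, limma's camera with Benjamini-Hochberg adjustment; adjusted p = 0.734 with an estimated correlation). None passed over all genes or adjusted over the list alone. The ATP synthase gene Atp5b had 1023 ± 78.8 and 929 ± 92.1 FPKM. Of 76 cytosolic ribosomal protein genes, 62 lay below the median of all genes, by a list median of −0.15 (adjusted p = 0.0013, limma's camera with Benjamini-Hochberg adjustment; adjusted p = 0.734 with an estimated correlation). The 1 member that passed, over all genes and adjusted over the list alone, was Rpl21, which rose. Rpl6, chosen after its values were seen, had 152 ± 16.5 and 107 ± 6.36 FPKM.

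**Figure D4:**
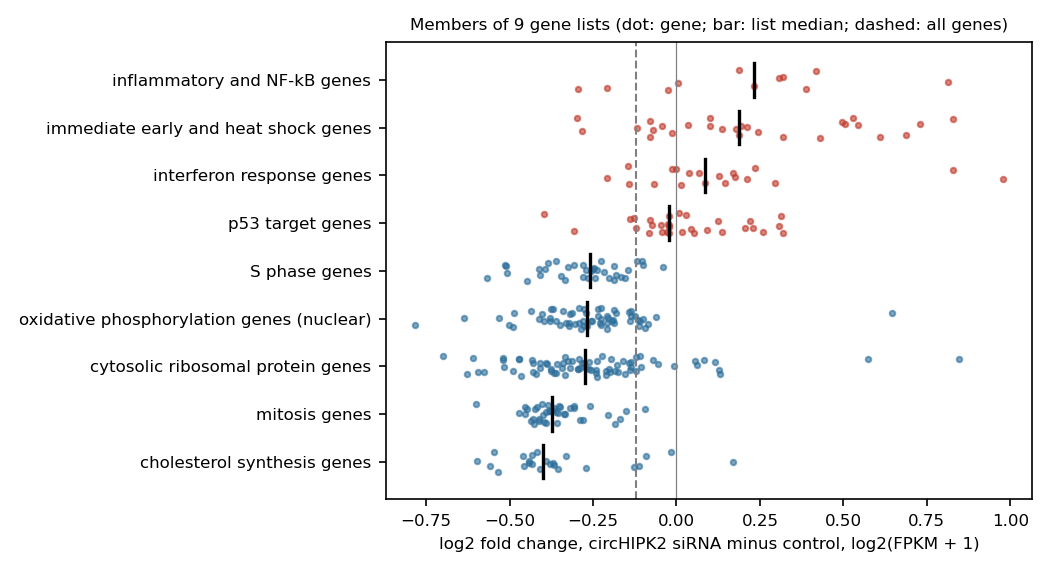
Log2 fold change (circHIPK2 siRNA minus control, on log2(FPKM + 1)) of each member (dot) of 9 gene lists, with the list median (bar), the median of all genes tested at −0.12 (dashed line) and 0 (solid line). In the immediate early and heat shock list 25 of 27 members lie above the dashed line, and in the mitosis list 39 of 40 lie below it.

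In all, 4 lists were higher and 5 lower of 24 tested. With an estimated correlation 0 were called (smallest adjusted p = 0.418, limma's camera with Benjamini-Hochberg adjustment), and with fry 0 were called (smallest adjusted p = 0.0985), with 10 lists at an unadjusted fry p below 0.05.

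Markers of neural cell types were not called as groups in the main test. Stem and progenitor markers (adjusted p = 0.108, limma's camera with Benjamini-Hochberg adjustment), neuronal markers (0.786), astrocyte markers (0.812) and oligodendrocyte lineage markers (0.101) had list medians 0.08 above, 0.02 below, 0.03 below and 0.13 below the median of all genes. For astrocyte markers the test had the opposite sign to the median. The oligodendrocyte list was called lower with median-of-ratios scaling (adjusted p = 0.011, limma's camera with Benjamini-Hochberg adjustment), quantile normalization (0.020), the loess correction (0.0069) and removal of the 9 entries (0.0014). On the values as deposited it was called lower without control library 1 (0.0075) or siRNA library 2 (0.0048), and with the replicate number as a block (0.0076). Stem markers were called higher with median-of-ratios scaling (0.040) and quantile normalization (0.015), and astrocyte markers with library weights (0.0018) and without control library 2 (0.0075). No member of these lists passed over all genes; adjusted over the list alone 1 stem marker (Hes5), 2 neuronal (Tubb3 and Stmn3), 0 astrocyte and 0 oligodendrocyte members fell. Fabp7, the fatty acid binding protein of radial glia, had 1206 ± 307 and 755 ± 148 FPKM, and Gap43, a growth cone gene, had 107 ± 15.9 and 96.6 ± 9.54 FPKM. Apoe, the astrocyte apolipoprotein, had 1103 ± 642 and 996 ± 465 FPKM, and the glial lineage transcription factor gene Olig1 had 452 ± 25.5 and 398 ± 53.7 FPKM. The sign of Gap43, Apoe and Olig1 turned under some settings. Tubb3, a neuronal tubulin gene, and Gpr17, a receptor gene of oligodendrocyte precursors, both chosen after their values were seen, had 8.12 ± 0.69 and 5.51 ± 0.79 FPKM, and 33.0 ± 7.88 and 18.8 ± 5.91 FPKM.

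Markers of other cell types were few at these levels. Of the microglial and of the vascular and fibroblast lists 2 members each were expressed above the filter, too few for a list test. Foxc1, a forkhead gene, had 1.66 ± 0.11 and 1.89 ± 0.14 FPKM, and Pdgfrl, the other vascular and fibroblast member, chosen after its values were seen, had 1.22 ± 0.27 and 0.784 ± 0.15 FPKM without passing. Cd68, a lysosomal gene of macrophages chosen after its values were seen, had 3.75 ± 0.72 and 6.15 ± 0.62 FPKM and rose adjusted over the list alone. The ependymal and choroid plexus list was not called (adjusted p = 0.373, limma's camera with Benjamini-Hochberg adjustment). Its test and median were positive and its mean of −0.27 negative, because Ttr is a member; adjusted over the list alone Foxj1, a regulator of motile cilia, rose and Ttr fell.

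Among the signalling lists the Notch pathway was not called (adjusted p = 0.229, limma's camera with Benjamini-Hochberg adjustment), although with no filter it was, as lower (0.020). With no filter the list was compared with 31660 entries, whose median log2 fold change was −0.016 against −0.12 with the filter. The list median of −0.12 is thus near that of the filtered genes, and this call does not set the list apart from them. Dll3 fell over all genes, and 3 members fell adjusted over the list alone. The other members of these 3, chosen after their values were seen, were the Notch effector gene Hes5 (17.2 ± 1.89 and 10.1 ± 1.05 FPKM) and the feedback regulator gene Nrarp (12.2 ± 0.35 and 7.01 ± 1.24 FPKM). The Wnt target list (adjusted p = 0.812, limma's camera with Benjamini-Hochberg adjustment), the BMP and TGF-beta list (0.496) and the growth factor list (0.108) were not called; the growth factor gene Pdgfa rose and Vegfb fell adjusted over the list alone. The cyclin gene Ccnd1 had 348 ± 32.6 and 333 ± 21.2 FPKM, the BMP target gene Id2 60.8 ± 9.57 and 54.7 ± 5.38 FPKM, and pleiotrophin, Ptn, 807 ± 26.4 and 691 ± 72.9 FPKM.

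The polyamine list, which contains Smox, was not called (adjusted p = 0.0684, limma's camera with Benjamini-Hochberg adjustment), with 16 of 20 members below the median of all genes and none past the test adjusted over the list alone. It was called lower with no filter (adjusted p = 3.65e-05, limma's camera with Benjamini-Hochberg adjustment), at a mean of at least 5 FPKM (0.038) and without siRNA library 3 (0.035). The call with no filter is again against entries with a median of −0.016 rather than −0.12. Eif5a, the translation factor that carries the polyamine-derived hypusine, had 263 ± 16.6 and 221 ± 18.9 FPKM. The lists of the unfolded protein and integrated stress response (adjusted p = 0.887, limma's camera with Benjamini-Hochberg adjustment), autophagy (0.254), glycolysis and hypoxia (0.328), mitochondrially encoded genes (0.641) and the extracellular matrix (0.328) were not called. Glycolysis and hypoxia genes were called higher with library weights (0.038), and mitochondrially encoded genes lower with quantile normalization (0.00038). For the unfolded protein and matrix lists the test had the opposite sign to the median. Their most abundant members were the chaperone gene Calr (247 ± 10.9 and 197 ± 30.8 FPKM), the lysosomal gene Lamp1 (326 ± 26.7 and 274 ± 44.9 FPKM), the pyruvate kinase gene Pkm (485 ± 117 and 360 ± 77.8 FPKM), mt-Co1 of cytochrome c oxidase (18668 ± 3741 and 15500 ± 1900 FPKM) and the proteoglycan gene Bcan (245 ± 14.6 and 214 ± 33.7 FPKM). In the matrix list Timp1, a metalloproteinase inhibitor gene, rose adjusted over the list alone. Members named only for passing in their own list were chosen after their values were seen.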

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

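The removal of liver genes, the removal of 9 entries at or rising with the ribosomal RNA locus and the loess correction were chosen after seeing the data. The 16 rises became 7 with no filter (1 of them shared with the 16), 4 with quantile normalization, 8 with robust moderation and 55 with library weights. They ranged from 2 to 15 when 1 library was left out. The 19 falls became 8 at a mean of at least 5 FPKM, 12 with quantile normalization, 265 with library weights and 5 without liver genes, and ranged from 6 to 23 when 1 library was left out. Without liver genes 10 of the falls could not be called by construction, and the adjustment was over fewer small p-values. For the others the cause was not tested. Lists called higher and lower became 0 and 0 with an estimated correlation, and 0 and 0 with fry. Fits without the trend and with robust moderation leave the list test unchanged and are not counted for lists. The 19 other settings all kept the preset correlation between genes, and some, such as 1 entry per symbol, barely differ from the main test. Over them, 7 of the 9 called lists were called in the same direction in all 19. The p53 list was called in 16 and the interferon list in 18. These counts do not test the preset correlation. With no filter, lists called lower were compared with entries whose median log2 fold change was −0.016 rather than −0.12, which favours a lower call. Hipk2 was not called in any of 21 settings, with a log2 fold change from −0.34 to −0.09 (adjusted p from 0.168 to 0.706, limma with Benjamini-Hochberg adjustment). Smox was not called in any either, at −1.60 to −0.55 (adjusted p from 0.138 to 0.478). The 21 settings leave out the thresholds with a fold of at least 2, whose counts are not given here. At an unadjusted p below 0.05 with such a fold Smox would pass (limma, unadjusted p = 0.0351, log2 fold change −1.24). Hipk2, at −0.29, would not.

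Some genes that never passed changed sign in log2 fold change, and the cause was not tested. With median-of-ratios scaling Hipk3 was at 0.018, Gap43 at 0.0015 and Ccnd1 at 0.077. With quantile normalization Hipk3 was at 0.0043, Gap43 at 0.044, Olig1 at 0.038, Ccnd1 at 0.18 and Id2 at 0.045. Without those 9 entries Hipk3 was at 0.073, Gap43 at 0.069, Apoe at 0.067, Olig1 at 0.016, Ccnd1 at 0.15, Id2 at 0.060 and Atp5b at 0.067. After the loess correction Hipk3 was at 0.0043, Gap43 at 0.012 and Ccnd1 at 0.051. With library weights Apoe was at 0.35 and Cx3cl1 at −0.071. When 1 library was left out, Apoe ranged from −0.42 to 0.34 (above 0 without control library 2 or siRNA library 3), B2m from −0.022 to 0.11 (below 0 without control library 1) and Cx3cl1 from −0.076 to 0.089 (below 0 without control library 2 or siRNA library 2).

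With the replicate number as a block, 23 genes were higher and 23 lower, with 4 lists higher and 6 lower, the added one being oligodendrocyte markers (adjusted p = 0.0076). Deviations of same-numbered libraries from their group means correlated at 0.05, 0.02 and 0.13, not all above 0.1, so the numbers were not taken as pairs. Not every library correlated best with its own number, as control library 2 did so with siRNA library 1 (0.12). Depth limits genes below about 0.05 FPKM, the value of 1 fragment for a 1 kb transcript.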

Other observations

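The liver, ribosomal RNA, poly(A), length and GC tests and the marker lists behind them were devised only after the calls had been seen, and the Alb to Apoa1 ratio, the depth ratio, poly(A) selection as the whole cause and the number of higher genes over other splits were tested with those values already known. The poly(A) and miR-124 verdicts also departed from the bounds written for them, as described with each.

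Liver transcripts outside the calls were also present in the control libraries. Serpina3k, a serine protease inhibitor gene of hepatocytes, had means of 1.62 and 0.0256 FPKM (controls and siRNA, n = 3 each), Hp, which encodes haptoglobin, 1.01 and 0.0162 FPKM, and Rbp4, the retinol carrier, 1.23 and 0.103 FPKM. The urinary protein gene Mup3 and the apolipoprotein gene Apoc3, at 1.69 and 1.53 FPKM in the controls, were listed at 0 in the siRNA libraries, as was the cytochrome gene Cyp2e1, at 0.879 FPKM. These genes were chosen after their values were seen. Of the hepatocyte list, Vtn and Arg1 are also in the vascular and polyamine lists.

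A candidate explanation is liver RNA in the control libraries, in culture or during library preparation. Of 47 detected hepatocyte genes outside the calls, 38 (80.9%) had all 3 controls above all 3 siRNA libraries, against 6.5% of 11556 other detected genes below a mean of 1 FPKM and 22.1% of all genes tested. Of the 47, 2, Trf and Ass1, reached a mean of 1 FPKM with the siRNA. RNA of other tissues was argued against, since 2 of 18 detected genes (11.1%) of the intestine (0 of 5), kidney (1 of 3), muscle (1 of 9) and pancreas (0 of 1) lists behaved so, and of the fetal liver and erythroid genes 0 of 8 did. The Alb to Apoa1 ratios of the 3 controls were 2.83, 6.35 and 5.36 (95% counting intervals 2.37 to 3.37, 4.84 to 8.34 and 4.31 to 6.66). They differed by up to 2.25 times, with control library 1 apart from the others beyond counting error. Whether 1 source entered the 3 controls stays open, since the intervals leave out other differences between libraries. The ratio cannot address the proportion, because that of 1 source is the same at any proportion. A response of the cells themselves to circHIPK2 silencing was not tested and stays open.

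Depth differed 1.063-fold between group means. FPKM is already divided by mapped fragments, so this ratio could not have shown depth as the cause of the rise at the ribosomal RNA locus. Less complete poly(A) selection of the siRNA libraries as the whole cause was tested only on RNAs with means of at least 1 FPKM. For 16 such small RNAs and histone genes the median log2 ratio of group means, relative to all genes, was 0.35 (95% bootstrap interval 0.07 to 0.72). Bootstrap intervals given here resampled genes, which are not independent, and leave out the spread between libraries. Whether each of the 16 lacks a poly(A) tail in these cells was not tested, and a minimum of 1 FPKM after oligo-dT selection can favour RNAs with tails. The highest of the 16 was 1.30, below the lowest of the 9 entries at or rising with the locus (1.97, highest 5.15). The upper bound of 0.72 also lay under 1.97, the result written as against poly(A) selection as the whole cause. Because of how the 16 were selected, this does not decide whether it was. Rn7sk, Rn7s2 and Rpph1, chosen after their values were seen, changed 1.16-fold, 1.56-fold and 2.23-fold. A part in the rise stays open, since over 84 detected such RNAs the median log2 fold change was 0.20 relative to all genes (95% bootstrap interval 0.16 to 0.25), which met the bound written against the explanation (under 0.25), but 68 of the 84 lay below 1 FPKM and the scale allows a median over the 84 of at most 0.91, under the 1 written for it. Of 23 small RNAs 0 had all controls above and 1 all siRNA libraries above, and of 61 histone genes 2 and 13. The 13 are 21.3%, against 8.4% of other detected genes below a mean of 1 FPKM. Below 1 FPKM some histone genes rose by more than Gm42418, the lowest of the 9 entries (3.55-fold). Hist2h2bb, chosen after its values were seen, rose 8.52-fold, from 0.0409 to 0.349 FPKM, within a few fragments of 0. Greater ribosomal RNA synthesis after silencing was not tested.

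At the preset correlation between genes, the list calls were not explained by a trend with transcript length and GC content alone. After the loess correction 9 of 9 lists kept their call and direction. Nor were the calls explained by siRNA library 3 alone, since 9 of 9 lists kept theirs without it. Neither fit tests the preset correlation. The 10 splits of the 6 libraries are too few for a share under 0.05. The real split called 9 lists, and the highest other split called 13, so 2 of 10 splits, the real one included, gave at least as many as the real one. For genes, the real split called 16 higher and 19 lower, and another split called at most 2 in a direction, so 1 of 10 splits reached each count.

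Circular RNAs from this gene have been proposed to bind miR-124, so its release was tested as a hypothesis through 7-mer sites (GTGCCTT) in 3' UTRs of 1942 genes. Genes with the site had higher, not lower, values with circHIPK2 siRNA (z = 3.39 after correction for UTR length and GC content), the opposite of what release would give. Only 3 of 16232 7-mers had a higher z, and in the other splits the absolute z of the site was at most 2.07. Another 7-mer reached −5.59 in another split, so a z of the size of 3.39 can arise from the spread of the libraries. The written bound against release was a z in the middle 90% of all 7-mers, which this was not, and counting a z above 3 against it was decided after the value was seen. miR-124 itself was not measured, so whether there was any to release is unknown. The sites gave no sign of release, but whether it occurred stays open. A seed effect of the siRNA on other mRNAs, tested as the lowest z over all 7-mers, gave −4.34 (CTCGTGC). Another split reached −5.59, counted in either direction, so no seed effect was told apart from the spread of the libraries.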
